A study of Homo sapiens with 18 samples.

How the data were processed

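Total RNA was sequenced (bulk RNA-seq) from CT27 cells, a human trophoblast stem cell line, on day 8 of differentiation into extravillous trophoblast (EVT) cells. Cells had received a control short hairpin RNA (shRNA) or an shRNA against CEBPB, ADAMTS20 or CCNB1. Each of the 3 experiments had 1 table with 3 control and 3 knockdown columns, 18 in all, and the experiment of each table was taken from the table's name. The submitters describe 3 biological replicates per condition. How many hairpins were used per target is not given in the sources used here.

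Per the labels, the authors used bcl2fastq 2.20.0.422, FastQC 0.11.9, R 4.2.2 and DESeq2 1.38.3 with the human build GRCh38.p13. A rat build, Rnor_5.0, is named beside it, and the aligner, the counting tool and the annotation are not given in the sources used here. The deposited values are a normalized signal: each column held whole multiples of 1 step, within a tolerance of 0.05, as gene counts divided by 1 size factor per library do. The authors' deposited table for each experiment also gives a log2 fold change of knockdown over control and an adjusted p-value. Every gene in the tables had an authors' adjusted p under 0.01 and an absolute log2 fold change of at least log2 of 1.5, so the tables hold selected genes and no unselected background. Repeated entries were dropped, 15 of 2618 for CEBPB, 9 of 2046 for ADAMTS20 and 9 of 1439 for CCNB1.

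The step of each column gave the relative depth of the libraries, taken as the size factor, and the whole reads of the listed genes. Total library depth cannot be had from selected genes. Comparison of recovered reads between tables showed that the 3 control columns of the ADAMTS20 and CCNB1 tables were the same 3 libraries, so that 15 libraries were distinct. Gene positions, transcript lengths and GC content were those of GENCODE release 29 on GRCh38, joined by gene identifier, with the longest transcript used for length and GC content. A transcript was found for 2598 of 2603, 2035 of 2037 and 1428 of 1430 genes.

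The gene lists, the rule for named genes and the tests were chosen before the data were examined, but the tests needed raw counts of all genes, which the tables do not hold, so limma was used in their place. Each experiment was fitted with limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, over its 6 libraries, with group as the only term, empirical Bayes moderation and a mean-variance trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the listed genes, with a threshold of 0.05. All tested genes had been selected by the authors on the same libraries, so the adjusted p-values here are not independent evidence. Differences between knockdown effects were tested with limma as knockdown minus control of one experiment minus that of another, over 12 libraries, or 9 where the controls were shared, for genes listed in both tables. For the pair with shared controls, the CCNB1 table was rescaled to the ADAMTS20 table by the ratio of the control values.

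In all, 35 gene lists of trophoblast states, cell cycle, signalling, stress, metabolism, matrix and other cell types were fixed in advance. They were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were listed, against the other listed genes, and adjusted over the lists. The targeted gene was left out of lists in its own experiment. Camera with an estimated correlation, fry and Fisher's exact test were run beside it.

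The rule for named genes took the targeted genes, the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups, up to 4 members per list, and 18 genes named in every experiment. For differences between knockdowns it took the 5 largest each way. The planned floor of 5 CPM needs library totals, so a mean of at least 200 normalized counts replaced it, chosen after the tables were seen. Genes with near-identical copies (CGB, PSG, CSH, histones, HLA) have uncertain read assignment.

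Alternatives were pseudocounts of 0.5 and 5, a filter of at least 10 normalized counts in at least 3 libraries, no mean-variance trend, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, and list tests after removal of a lowess trend on transcript length or GC content with a span of 0.5. The list tests after a correction used the pre-ranked form of camera, on the corrected log2 fold change divided by its SE. Pre-ranked camera was not run without a correction, so a change from camera cannot be put down to length or GC content alone. The fits were tested on simulated data with 200 changed genes. At a log2 fold change of 1 they recovered 98%, 96% and 98% of changed genes for CEBPB, ADAMTS20 and CCNB1. Of unchanged genes, 0.250%, 0.435% and 0.407% were called. The simulated dispersion was fixed at 0.01, so these shares do not measure recovery of genes with a wider spread. Lists of 20 genes moving one way were called in 70%, 88% and 34% of simulations, and random lists in 1.11%, 0% and 0.667%. Simulated genes varied independently of each other, with an SD of 0.15. These shares therefore do not measure how often camera calls lists of correlated genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation and plots.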

Results

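Transcript levels were measured by bulk RNA-seq in CT27 trophoblast stem cells differentiated for 8 days into EVT cells, the placental cells that invade the uterine wall. In each of 3 experiments, 3 libraries from cells with a control shRNA were set against 3 from cells with an shRNA against CEBPB, ADAMTS20 or CCNB1. The ADAMTS20 and CCNB1 experiments shared their control libraries: recovered reads were equal in 100% of the 478 genes found in both tables, against at most 2.30% for any other pair of libraries from different tables. Tables held 2603 genes for CEBPB, 2037 for ADAMTS20 and 1430 for CCNB1, all chosen by the authors for a difference between the same libraries. A gene absent from a table therefore either missed the authors' limits or was not tested, and the folds nearest the limit are prone to overstatement by that choice.

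Recovered reads in listed genes ranged from 6692644 to 11867761 per library for CEBPB, from 4036702 to 6197698 for ADAMTS20 and from 1270317 to 3835835 for CCNB1. Relative depth was 0.790 to 1.19 over both CEBPB groups. It was 0.650 to 1.03 in controls and 0.998 to 1.31 in knockdown libraries of the ADAMTS20 table. In the CCNB1 table it was 0.569 to 0.887 in controls and 1.21 to 1.42 in knockdown libraries, so relative depth and group went together there. A single read stood for 0.703 to 1.76 normalized counts, and this counting step limits precision for genes with few reads. Values are given as mean ± SD of normalized counts (n = 3 libraries per group), and log2 fold changes of knockdown over control as estimate ± SE from limma.

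CEBPB encodes a basic leucine zipper transcription factor, and this comparison asked which transcripts differed on day 8 when it was targeted. Of 43 EVT markers 25 were lower after CEBPB knockdown and 18 were not listed, and of 35 interferon response genes 28 were higher and 7 were not listed. Neither list passed camera with an estimated correlation (adjusted p = 0.682 and 0.682). HLA-G, the class I molecule characteristic of EVT cells, fell from 54660.0 ± 5954 to 17011 ± 2209 normalized counts, a log2 fold change of -1.69 ± 0.16. FLT4, which encodes a receptor for vascular endothelial growth factors C and D, fell from 4193 ± 1301 to 439 ± 83.6 normalized counts, or -3.22 ± 0.21 on the log2 scale. OAS2, an interferon-induced antiviral enzyme, rose from 9.86 ± 7.90 to 430.2 ± 112 normalized counts, or 5.51 ± 0.38 on the log2 scale.

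All 25 listed genes of the 43 EVT markers fell after CEBPB knockdown, with a median log2 fold change of -1.23. They included NOTUM, a secreted enzyme that inactivates WNT proteins (-2.18 ± 0.19), the matrix metalloproteinase MMP2 (-1.23 ± 0.19), the activin-binding protein FSTL3 (-1.06 ± 0.21) and the transcription factor ASCL2 (-1.14 ± 0.17). Camera gave an adjusted p of 2.49e-07 for the list, and 0.682 as the adjusted p with an estimated correlation. The 28 listed genes of the 35 in the interferon response list all rose, with a median log2 fold change of 2.16. Among them were IFIT1 (4.08 ± 0.33), MX1 (3.80 ± 0.25) and OAS1 (4.59 ± 0.40). The camera adjusted p was 9.95e-07, against an adjusted p of 0.682 with an estimated correlation.

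Of 41 syncytiotrophoblast markers, genes of the fused hormone-secreting layer of the placenta, 28 rose and 5 fell after CEBPB knockdown. CYP19A1, the aromatase that makes estrogens, rose from 8989 ± 1077 to 37866 ± 1359.7 normalized counts, or 2.08 ± 0.15 on the log2 scale. The common hormone subunit gene CGA rose by 1.08 ± 0.22 and SDC1 by 0.80 ± 0.18. Placental lactogen genes went the other way, with log2 fold changes of -2.24 ± 0.18 for CSH1 and -2.21 ± 0.17 for CSH2, whose near-identical sequences leave the assignment of reads uncertain. The same holds for CGB and PSG genes among the rises, so the 28 and 5 do not count independent genes. Camera gave an adjusted p of 0.0348 for the list, and 0.745 as the adjusted p with an estimated correlation. The call ended without control replicate 2 (adjusted p = 0.0535) and with the replicate number as a block (0.0769). Pre-ranked camera gave an adjusted p of 0.0702 after a GC correction and 0.0648 after a length correction. These values come from another form of the test, so they do not show an effect of GC content or length.

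In the hypoxia and glycolysis list, 8 of 9 listed genes were lower after CEBPB knockdown, among them the collagen prolyl hydroxylases P4HA1 (-1.48 ± 0.16) and P4HA2 (-1.35 ± 0.15) and the glycolytic aldolase ALDOC (-1.03 ± 0.18). The camera adjusted p was 0.0435, with an adjusted p of 0.682 under an estimated correlation, and the call ended without control replicate 1 (adjusted p = 0.0507) or control replicate 2 (0.0535), with the replicate number as a block (0.0769) and by Fisher's exact test (0.0813). Among genes with a mean of at least 200 normalized counts, the 10 largest rises also included OLR1, a receptor for oxidized low-density lipoprotein (4.09 ± 0.19), the hemidesmosome collagen COL17A1 (3.72 ± 0.23) and the microfibril protein FBN2 (3.71 ± 0.20). The 10 largest falls under that limit included the proteoglycans VCAN (-3.17 ± 0.26) and ACAN (-2.83 ± 0.19), and SCUBE1 (-3.03 ± 0.30), PTH1R (-2.74 ± 0.20) and RET (-2.39 ± 0.19). Of the genes named in every experiment, CDKN1C (-0.85 ± 0.17) and ISM2 (-1.30 ± 0.19) fell, CDKN1A (0.59 ± 0.17) and LRP5 (1.00 ± 0.19) rose, and ITGA1, TEAD4, TP63, ITGA6, MKI67 and LAIR2 were not among the listed genes.

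In total 1446 genes were higher and 1157 lower after CEBPB knockdown. All 2603 passed limma, and the groups did not overlap in 2576 of them, against 10% by chance. HLA-G is ENSG00000204632, on chromosome 6 from 29826967 to 29831125, FLT4 is ENSG00000037280, on chromosome 5 from 180601506 to 180649624, and OAS2 is ENSG00000111335, on chromosome 12 from 112978395 to 113011723, all on GRCh38. CEBPB itself was not among the genes of the table analysed here, nor were ADAMTS20 and CCNB1, so the table does not show a fall of CEBPB. With 14869 ± 1727 normalized counts in the controls of the ADAMTS20 experiment, CEBPB was not a low transcript there, and its absence leaves open that its mRNA missed the authors' limits of 1.5-fold and an adjusted p of 0.01. Selection by the authors on these libraries means that neither the gene count nor the lack of overlap is an independent test.

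**Figure D1:**
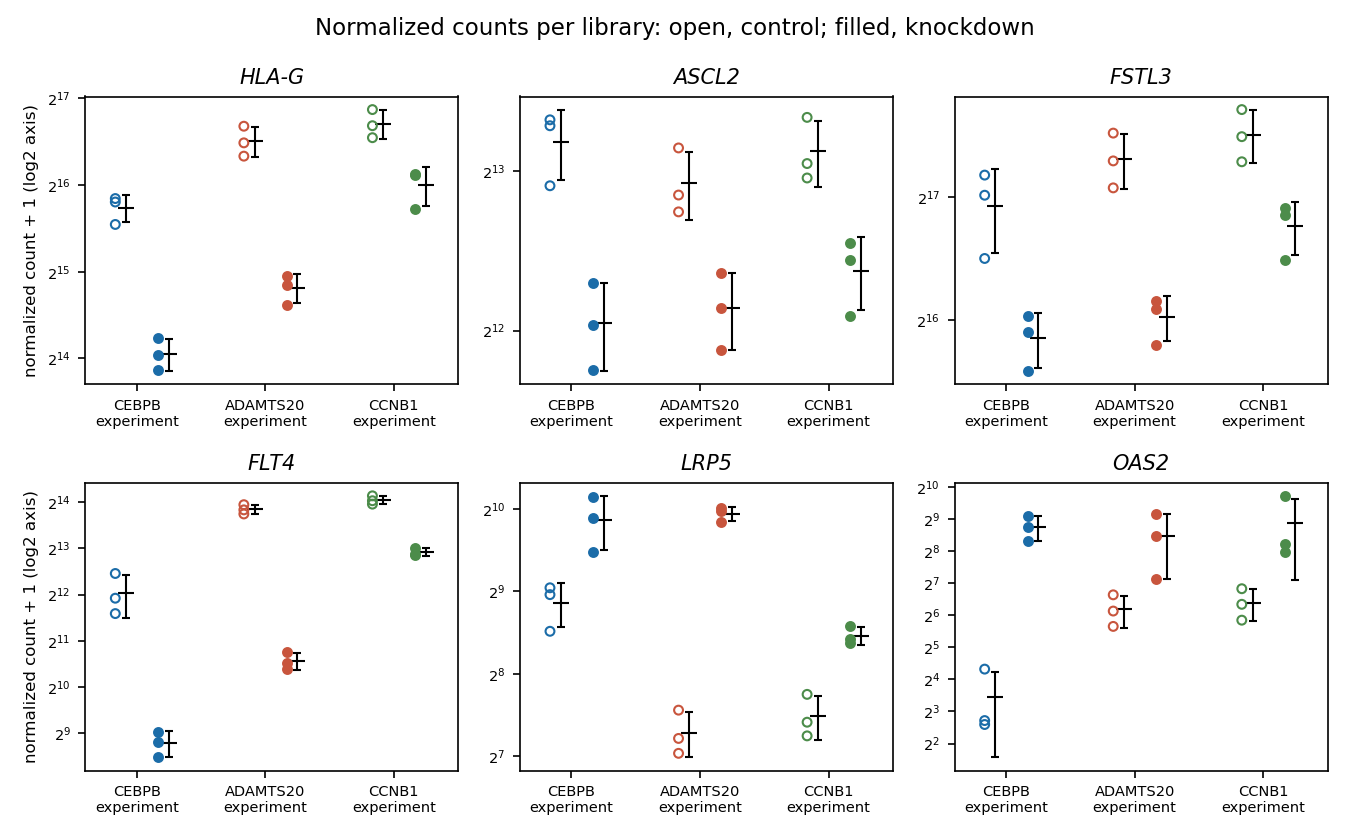
Normalized counts plus 1 on a log2 axis for HLA-G, ASCL2, FSTL3, FLT4, LRP5 and OAS2 in each library of the CEBPB, ADAMTS20 and CCNB1 experiments, with open points for control and filled points for knockdown libraries and bars for the mean ± SD of 3 libraries. HLA-G and FLT4 lie lower in the knockdown libraries of all 3 experiments, and OAS2 lies higher, with its largest rise after CEBPB knockdown (log2 fold change 5.51).

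Of the remaining lists tested for CEBPB knockdown, listed members numbered 11 higher and 3 lower of 27 for stem cell and cytotrophoblast markers, 3 higher and 0 lower of 8 for column cytotrophoblast markers and 7 higher and 0 lower of 43 for S phase genes. Further counts were 8 higher and 3 lower of 35 for cyclins, CDKs and CDK inhibitors, 7 higher and 0 lower of 42 for replication-dependent histones and 5 higher and 0 lower of 30 for p53 targets. The same count gave 3 higher and 8 lower of 43 for the ADAMTS, MMP and TIMP family, 10 higher and 15 lower of 46 for extracellular matrix proteins and 7 higher and 3 lower of 28 for epithelial adhesion genes. Other tested lists had 5 higher and 3 lower of 18 for mesenchymal and EMT regulators, 5 higher and 2 lower of 19 for C/EBP and AP-1 genes and 5 higher and 2 lower of 30 for NF-kB and cytokine genes. Next came 0 higher and 5 lower of 16 for MHC class I genes, 7 higher and 1 lower of 30 for stress response and unfolded protein genes and 3 higher and 0 lower of 25 for cholesterol synthesis genes. In addition there were 5 higher and 0 lower of 15 for steroid hormone synthesis genes, 1 higher and 4 lower of 24 for WNT pathway genes and 4 higher and 1 lower of 20 for NOTCH pathway genes. More tested lists had 7 higher and 4 lower of 32 for TGF-beta and BMP pathway genes, 4 higher and 4 lower of 22 for angiogenic and vasoactive factors and 2 higher and 2 lower of 9 for amnion and ectoderm-like markers. Counts were also 1 higher and 2 lower of 11 for stromal and decidual fibroblast markers, 6 higher and 1 lower of 19 for immediate early genes and 3 higher and 0 lower of 16 for heat shock proteins. Then there were 2 higher and 5 lower of 20 for imprinted genes. Lists with too few listed genes for a test had 1 higher and 0 lower of 55 for G2/M genes, 0 higher and 1 lower of 11 for macrophage and leukocyte markers, 0 higher and 1 lower of 9 for endothelial markers and 0 higher and 1 lower of 59 for cytosolic ribosomal proteins. No member was listed of the 13 mitochondrially encoded mRNAs or the 47 nuclear oxidative phosphorylation genes. None of the tested lists in this paragraph passed camera, with adjusted p from 0.0750 to 0.957. Lists whose median, mean and test differed in sign were the angiogenic and the amnion lists.

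ADAMTS20 encodes a secreted metalloprotease, and this comparison asked which transcripts differed when it was targeted. ADAMTS20 itself was 11111, 20037 and 14753 normalized counts in the control libraries and 2666, 2532 and 4480.0 in the knockdown libraries, a log2 fold change of -2.25 ± 0.21 (limma adjusted p = 6.29e-07). Of 55 G2/M genes 45 were higher, of 27 stem cell and cytotrophoblast markers 14 were higher and 3 lower, and of 43 EVT markers 20 were lower and 4 higher, the others not being listed. With an estimated correlation none of these lists passed (adjusted p = 0.188, 0.399 and 0.741). TOP2A, the topoisomerase of dividing cells, rose from 229.8 ± 55.7 to 1436 ± 267 normalized counts, or 2.65 ± 0.17 on the log2 scale. HLA-G fell from 93162 ± 11224 to 28819 ± 3319 normalized counts, or -1.69 ± 0.12 on the log2 scale.

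The 45 listed genes of the 55 in the G2/M list all rose after ADAMTS20 knockdown, with a median log2 fold change of 1.64. Examples were the mitotic kinase CDK1 (2.64 ± 0.18), NEK2 (2.33 ± 0.29), the kinetochore gene NDC80 (2.23 ± 0.30) and the proliferation marker MKI67 (1.90 ± 0.11). The camera adjusted p was 7.58e-08, against an adjusted p of 0.188 with an estimated correlation. All 35 listed genes of 43 in the S phase list rose too, with UHRF1 (1.87 ± 0.16) and BLM (1.65 ± 0.16) among them. Camera gave them an adjusted p of 5.27e-06, and 0.188 as the adjusted p with an estimated correlation. All 19 listed cyclins, CDKs and CDK inhibitors of 35 rose, by 0.60 to 4.36 on the log2 scale, among them CCND2 (4.36 ± 0.49), CCND1 (2.53 ± 0.12) and CCNB1 (1.01 ± 0.11), with a camera adjusted p of 5.62e-04 and an adjusted p of 0.263 with an estimated correlation. Several genes, such as CDK1 and CCNB1, stand in more than 1 of these lists.

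Of 27 stem cell and cytotrophoblast markers, 14 rose and 3 fell after ADAMTS20 knockdown. The WNT co-receptor LRP5 rose from 155 ± 29.4 to 983 ± 59.6 normalized counts, or 2.67 ± 0.14 on the log2 scale, and the imprinted gene PEG10 by 2.85 ± 0.09. TP63 and TEAD4, transcription factors of trophoblast progenitors, rose by 1.48 ± 0.29 and 1.35 ± 0.16, and the integrin ITGA6 by 1.28 ± 0.08. Camera gave an adjusted p of 0.0295, and 0.399 as the adjusted p with an estimated correlation; by Fisher's exact test it was 0.0995.

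Among EVT markers, 20 genes fell and 4 rose after ADAMTS20 knockdown. EBI3, a subunit of interleukins 27 and 35, fell from 3809.7 ± 918 to 197 ± 41.9 normalized counts, or -4.26 ± 0.17 on the log2 scale. FLT4 (-3.29 ± 0.10), PLAC8 (-2.18 ± 0.16), FSTL3 (-1.29 ± 0.14), MMP2 (-1.03 ± 0.13) and ASCL2 (-0.79 ± 0.13) were lower, while LAIR2 (0.99 ± 0.14) was higher. The camera adjusted p was 5.02e-04, against an adjusted p of 0.741 with an estimated correlation. CEBPB, the target of another experiment, fell from 14869 ± 1727 to 7820.0 ± 893 normalized counts, or -0.93 ± 0.11 on the log2 scale.

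Further large rises after ADAMTS20 knockdown were the prostaglandin transporter SLCO2A1 (4.54 ± 0.25), OLR1 (4.16 ± 0.25), GPRC5A (3.68 ± 0.16), the chemokine CXCL14 (3.53 ± 0.15) and the collagen COL12A1 (3.11 ± 0.18). Large falls included SCUBE1 (-3.56 ± 0.11), GPR146 (-3.17 ± 0.16), S100A6 (-2.92 ± 0.12) and the prostaglandin D synthase PTGDS (-2.76 ± 0.11). CGA fell by 0.75 on the log2 scale and the interferon-induced gene OAS2 rose by 2.11 ± 0.40. ISM2 was lower (-1.04 ± 0.14), and ITGA1, NOTUM, SDC1, CDKN1C and CDKN1A were not among the listed genes.

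In total 1099 genes were higher and 938 lower after ADAMTS20 knockdown. All 2037 passed limma, and groups did not overlap in 2027 of them, against 10% by chance in unselected genes. The authors had selected these genes on the same libraries, so neither count is an independent test. ADAMTS20 is ENSG00000173157, on chromosome 12 from 43353866 to 43551921, TOP2A is ENSG00000131747, on chromosome 17 from 40388516 to 40417950, and EBI3 is ENSG00000105246, on chromosome 19 from 4229498 to 4237531, all on GRCh38. Genes that rose had a median transcript GC content of 47.5%, against 55.2% in genes that fell, and the listed G2/M genes had a median of 42.6%. In pre-ranked camera after a GC correction, the adjusted p was 3.82e-06 for G2/M, 0.00190 for S phase and 3.82e-06 for EVT markers. Without that correction, camera at the preset correlation gave these lists an adjusted p of 7.58e-08, 5.27e-06 and 5.02e-04. Camera with an estimated correlation gave 0.188, 0.188 and 0.741. The form of the test differed as well as the correction, so no change can be put down to GC content alone.

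Of the remaining lists tested for ADAMTS20 knockdown, listed members numbered 4 higher and 1 lower of 8 for column cytotrophoblast markers, 5 higher and 12 lower of 41 for syncytiotrophoblast markers and 7 higher and 0 lower of 30 for p53 targets. Further counts were 3 higher and 5 lower of 42 for the ADAMTS, MMP and TIMP family, 13 higher and 10 lower of 46 for extracellular matrix proteins and 5 higher and 2 lower of 28 for epithelial adhesion genes. The same count gave 5 higher and 3 lower of 18 for mesenchymal and EMT regulators, 1 higher and 7 lower of 20 for C/EBP and AP-1 genes and 1 higher and 3 lower of 30 for NF-kB and cytokine genes. Other tested lists had 7 higher and 3 lower of 35 for interferon response genes, 3 higher and 1 lower of 30 for stress response and unfolded protein genes and 1 higher and 6 lower of 35 for hypoxia and glycolysis genes. Next came 2 higher and 1 lower of 15 for steroid hormone synthesis genes, 3 higher and 3 lower of 24 for WNT pathway genes and 3 higher and 3 lower of 20 for NOTCH pathway genes. In addition there were 5 higher and 4 lower of 32 for TGF-beta and BMP pathway genes, 5 higher and 7 lower of 22 for angiogenic and vasoactive factors and 2 higher and 1 lower of 9 for endothelial markers. More tested lists had 3 higher and 8 lower of 19 for immediate early genes and 3 higher and 2 lower of 20 for imprinted genes. Lists with too few listed genes for a test had 0 higher and 1 lower of 42 for replication-dependent histones, 0 higher and 2 lower of 16 for MHC class I genes, 2 higher and 0 lower of 25 for cholesterol synthesis genes and 2 higher and 0 lower of 9 for amnion and ectoderm-like markers. Such short lists also had 0 higher and 1 lower of 11 for stromal and decidual fibroblast markers, 0 higher and 1 lower of 11 for macrophage and leukocyte markers, 1 higher and 1 lower of 16 for heat shock proteins and 2 higher and 0 lower of 47 for nuclear oxidative phosphorylation genes. No member was listed of the 13 mitochondrially encoded mRNAs or the 59 cytosolic ribosomal proteins. None of the tested lists in this paragraph passed camera, with adjusted p from 0.0565 to 0.935. The WNT, NOTCH and TGF-beta lists differed in sign between median, mean and test.

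**Figure D2:**
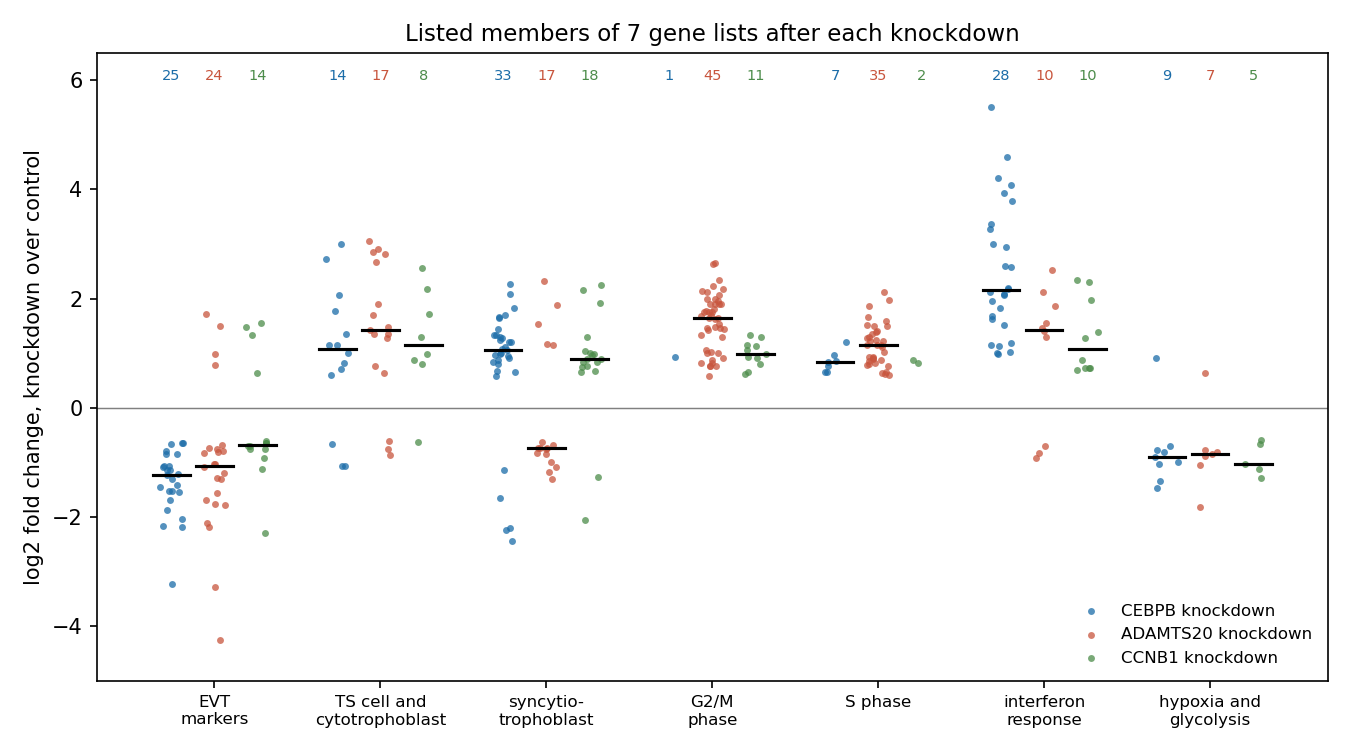
Log2 fold change of each listed member of 7 gene lists after CEBPB, ADAMTS20 or CCNB1 knockdown, with 1 point per gene. EVT markers lie mostly under 0 in all 3 experiments, the G2/M and S phase genes rose after ADAMTS20 knockdown (medians 1.64 and 1.15), and interferon response genes rose after CEBPB knockdown (median 2.16).

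CCNB1 encodes cyclin B1, which drives entry into mitosis with the kinase CDK1, and this comparison asked which transcripts differed when it was targeted. After CCNB1 knockdown, 5 of 35 hypoxia and glycolysis genes were lower, and of 43 EVT markers 10 were lower and 4 higher, the others not being listed. Neither list passed camera with an estimated correlation (adjusted p = 0.799 and 0.799). SLC2A3, a glucose transporter, fell from 13084 ± 1966 to 5351 ± 906 normalized counts, or -1.29 ± 0.16 on the log2 scale. FLT4 fell from 16925 ± 1067 to 7747 ± 478 normalized counts, or -1.13 ± 0.11 on the log2 scale. TFPI2, a protease inhibitor made by the placenta, rose from 1582 ± 157 to 7563 ± 1015 normalized counts, or 2.25 ± 0.15 on the log2 scale. ADAMTS20, the target of another experiment, rose from 17613 ± 5299 to 34898 ± 4385 normalized counts, or 1.02 ± 0.20 on the log2 scale (limma adjusted p = 0.00164).

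All 5 listed genes of the hypoxia and glycolysis list fell after CCNB1 knockdown, including LDHA (-1.13 ± 0.15), ALDOC (-1.03 ± 0.18) and ENO1 (-0.67 ± 0.14). The camera adjusted p was 0.0132, against an adjusted p of 0.799 with an estimated correlation. Pre-ranked camera gave an adjusted p of 0.00364 after a GC correction. Of 43 EVT markers, 10 fell and 4 rose: HLA-G (-0.71 ± 0.14), ASCL2 (-0.75 ± 0.16), FSTL3 (-0.75 ± 0.14) and AOC1 (-2.30 ± 0.27) were lower, and the metalloprotease PAPPA (1.33 ± 0.15), HPGD (1.56 ± 0.19) and TAC3 (1.47 ± 0.27) higher. Camera gave this list an adjusted p of 0.0360, and 0.799 as the adjusted p with an estimated correlation. The EVT list missed the threshold in pre-ranked camera after a length correction (adjusted p = 0.121) and after a GC correction (0.933). Another form of the test was used there, so the loss cannot be put down to length or GC content alone.

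In the syncytiotrophoblast list 16 genes were higher and 2 lower after CCNB1 knockdown, with KISS1, the kisspeptin precursor, higher (2.16 ± 0.18) and CRH, the corticotropin-releasing hormone gene, lower (-2.05 ± 0.39). The rises included PSG genes, near-identical copies with uncertain read assignment. The list missed the camera threshold (adjusted p = 0.0646), with an adjusted p of 0.799 under an estimated correlation. In pre-ranked camera it passed after a length correction (adjusted p = 0.000833) but not after a GC correction (0.0567). The 8 listed stem cell and cytotrophoblast markers were 7 higher and 1 lower, with PAGE4 (2.55 ± 0.25) and PEG10 (2.18 ± 0.13) as the largest rises in the list. Camera gave these markers an adjusted p of 0.194, and an adjusted p of 0.799 with an estimated correlation. Pre-ranked camera gave an adjusted p of 0.00299 after a GC correction. Listed matrix genes were 9 higher and 3 lower, with FBN2 (3.03 ± 0.19) and POSTN (2.74 ± 0.36) higher and COL6A2 (-2.77 ± 0.29) lower. Their camera adjusted p was 0.367, and the adjusted p with an estimated correlation 0.799. After a GC correction, pre-ranked camera gave an adjusted p of 0.00730. All 11 listed G2/M genes of 54 were higher, among them CENPE (1.32 ± 0.27), TOP2A (1.15 ± 0.19) and CDK1 (1.13 ± 0.20). Their adjusted p was 0.156 by camera, and 0.790 by pre-ranked camera after a GC correction. Pre-ranked camera was not run without a correction, so none of these changes can be put down to length or GC content alone.

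Other large rises after CCNB1 knockdown were OLR1 (3.46 ± 0.29), the transcription factor RUNX3 (2.29 ± 0.35), ADAMTSL1 (2.40 ± 0.39) and the peptidase MME (2.07 ± 0.17). Large falls were the imprinted gene NDN (-2.79 ± 0.18), the troponin TNNT1 (-2.46 ± 0.23), the cancer-testis gene MAGEA4 (-2.37 ± 0.22) and SBSN (-2.28 ± 0.17). MKI67 rose by 0.65 ± 0.16 and LRP5 by 0.99 ± 0.17. ITGA1, MMP2, NOTUM, TEAD4, TP63, ITGA6, CGA, SDC1, CDKN1C, CDKN1A, ISM2 and LAIR2 were not among the listed genes.

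In total 991 genes were higher and 439 lower after CCNB1 knockdown. All 1430 passed limma, and the groups did not overlap in any of the 1430, where chance gives no overlap in 10% of unselected genes. Neither count is an independent test, because the authors had selected these genes on the same libraries. Genes that rose had a median transcript GC content of 40.6% and genes that fell 56.5%, a difference of -15.9 percentage points. The relative depth of the controls was lower than that of the knockdown libraries. SLC2A3 is ENSG00000059804, on chromosome 12 from 7919230 to 7936275, TFPI2 is ENSG00000105825, on chromosome 7 from 93885396 to 93890991, and OLR1 is ENSG00000173391, on chromosome 12 from 10158301 to 10172138, all on GRCh38. CCNB1 itself was not among the genes of the table analysed here, nor was CEBPB, so the table does not show a fall of CCNB1. CCNB1 was measured in the same control libraries (2159.9 ± 264 normalized counts in the ADAMTS20 table), and its absence leaves open that its mRNA missed the authors' limits of 1.5-fold and an adjusted p of 0.01.

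**Figure D3:**
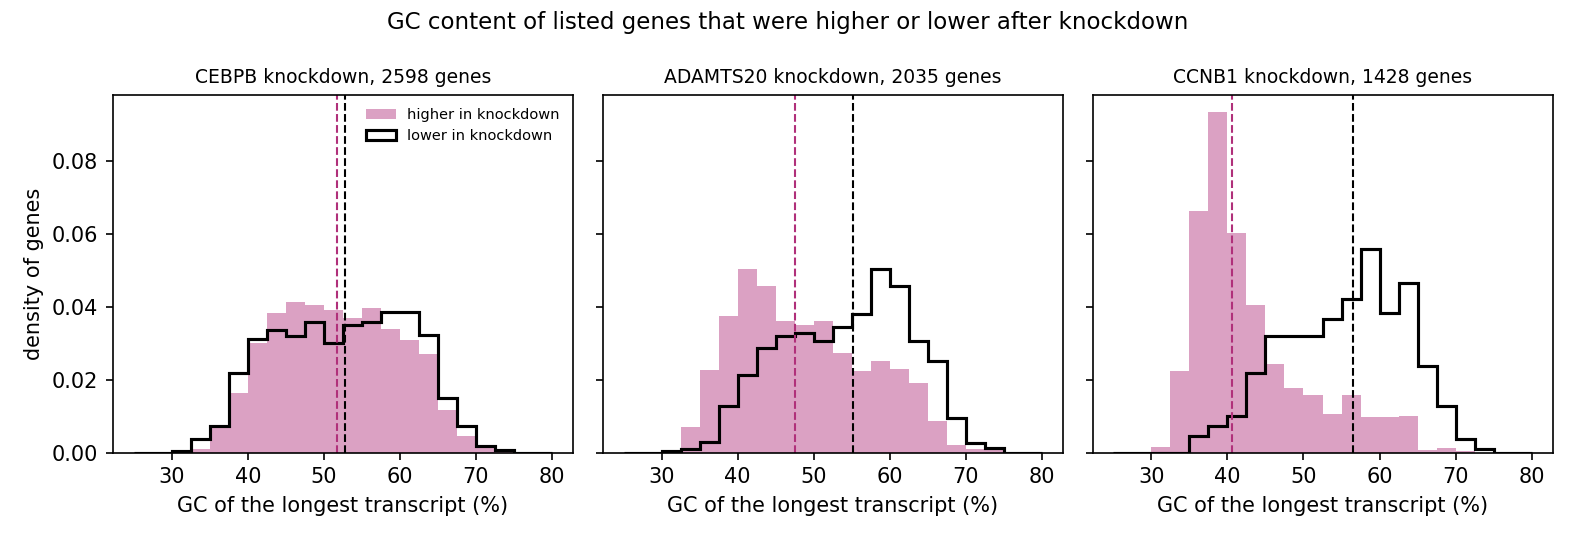
Density of GC content (%) of the longest transcript for listed genes that were higher (filled) or lower (outline) after CEBPB, ADAMTS20 and CCNB1 knockdown. The medians of higher and lower genes differ by -1.15 percentage points for CEBPB, -7.66 for ADAMTS20 and -15.9 for CCNB1.

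Of the remaining lists tested for CCNB1 knockdown, listed members numbered 3 higher and 0 lower of 34 for cyclins, CDKs and CDK inhibitors, 5 higher and 1 lower of 30 for p53 targets and 4 higher and 2 lower of 43 for the ADAMTS, MMP and TIMP family. Further counts were 2 higher and 2 lower of 28 for epithelial adhesion genes, 0 higher and 4 lower of 18 for mesenchymal and EMT regulators and 10 higher and 0 lower of 35 for interferon response genes. The same count gave 4 higher and 0 lower of 15 for steroid hormone synthesis genes, 1 higher and 3 lower of 20 for NOTCH pathway genes and 6 higher and 2 lower of 32 for TGF-beta and BMP pathway genes. Other tested lists had 3 higher and 2 lower of 22 for angiogenic and vasoactive factors, 2 higher and 1 lower of 19 for immediate early genes and 2 higher and 1 lower of 20 for imprinted genes. Lists with too few listed genes for a test had 1 higher and 0 lower of 8 for column cytotrophoblast markers, 2 higher and 0 lower of 43 for S phase genes, 2 higher and 0 lower of 42 for replication-dependent histones and 1 higher and 1 lower of 20 for C/EBP and AP-1 genes. Such short lists also had 1 higher and 0 lower of 30 for NF-kB and cytokine genes, 0 higher and 2 lower of 16 for MHC class I genes, 1 higher and 0 lower of 30 for stress response and unfolded protein genes and 1 higher and 1 lower of 24 for WNT pathway genes. Such short lists also had 1 higher and 1 lower of 9 for amnion and ectoderm-like markers, 0 higher and 2 lower of 9 for endothelial markers, 1 higher and 0 lower of 16 for heat shock proteins and 0 higher and 1 lower of 59 for cytosolic ribosomal proteins. No member was listed of the 25 cholesterol synthesis genes, the 11 stromal and decidual fibroblast markers, the 11 macrophage and leukocyte markers, the 13 mitochondrially encoded mRNAs or the 47 nuclear oxidative phosphorylation genes. None of the tested lists in this paragraph passed camera, with adjusted p from 0.0555 to 0.954. The ADAMTS, MMP and TIMP list and the angiogenic list differed in sign between median, mean and test.

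For every list in the 3 experiments, the number of members called when adjusted over the list alone equalled the number called over all listed genes. None of the list calls passed the threshold with an estimated correlation, where camera gave 0 lists in each experiment, and at an unadjusted p under 0.05 gave 1 list for CEBPB, 3 for ADAMTS20 and 0 for CCNB1. By fry, which tests movement within a list and not against other genes, 25, 23 and 16 lists passed. All listed genes had been selected by the authors for a change between these libraries. That selection favours passing fry, and with every gene called, the equal counts over the list alone were fixed in advance.

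The effects of pairs of knockdowns were compared over the genes listed for both. CEBPB and ADAMTS20 knockdown shared 780 listed genes, of which 361 rose in both, 270 fell in both and 149 went opposite ways. The effects differed in 321 of them by limma's test of the difference. Control libraries were not shared between these experiments, so the test cannot tell target from experiment. CGA was among the opposite genes, with a difference in log2 fold change of 1.83 ± 0.20 (adjusted p = 3.05e-07), and so was PECAM1, an adhesion molecule of endothelium and leukocytes, at -3.48 ± 0.22 (adjusted p = 4.16e-10). For FLT4, which fell in both, the difference of 0.06 ± 0.26 missed the threshold (adjusted p = 0.880), which does not show that the effects were equal.

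CEBPB and CCNB1 knockdown shared 526 listed genes, with 332 higher in both, 138 lower in both and 56 opposite. The effects differed in 191 genes, among them the interferon-induced genes OAS2 and MX1, both with the larger rise after CEBPB knockdown. Target and experiment cannot be told apart here either, because the control libraries were not shared. By limma the difference was 3.20 ± 0.64 for OAS2 (adjusted p = 7.63e-04) and 3.07 ± 0.38 for MX1 (adjusted p = 8.23e-06). ADAMTS20 and CCNB1 knockdown shared 478 listed genes, with 230 higher in both, 202 lower in both and 46 opposite, and differed in 208. The same direction was found in 90.4%. In 100 simulations of unchanged groups against the shared controls, a mean of 3.70 of 478 genes passed the fold limit in both, and 96.8% of those had the same direction, so the share of 90.4% alone does not separate a shared change from shared controls. The difference, ADAMTS20 minus CCNB1 knockdown, was -3.33 ± 0.19 for EBI3 (adjusted p = 1.07e-08) and 3.81 ± 0.15 for NDN (adjusted p = 9.13e-10).

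Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.701 for CEBPB with ADAMTS20, 0.717 for CEBPB with CCNB1 and 0.810 for ADAMTS20 with CCNB1, and Spearman's rho was 0.664, 0.681 and 0.810. The covariances were 1.60, 1.17 and 1.91. For the last pair, simulated groups with no change against the shared controls gave a mean covariance of 0.0253 over the same number of genes, not selected by fold. All 3 tables listed 254 genes, of which 137 were higher and 79 lower in every experiment. OLR1, LAMB4, MARCHF4 and FBN2 were higher in each, and DPEP1, DLL1, PRDM16 and PNCK lower in each, the 4 genes each way whose smallest change was largest, chosen after the values were seen.

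**Figure D4:**
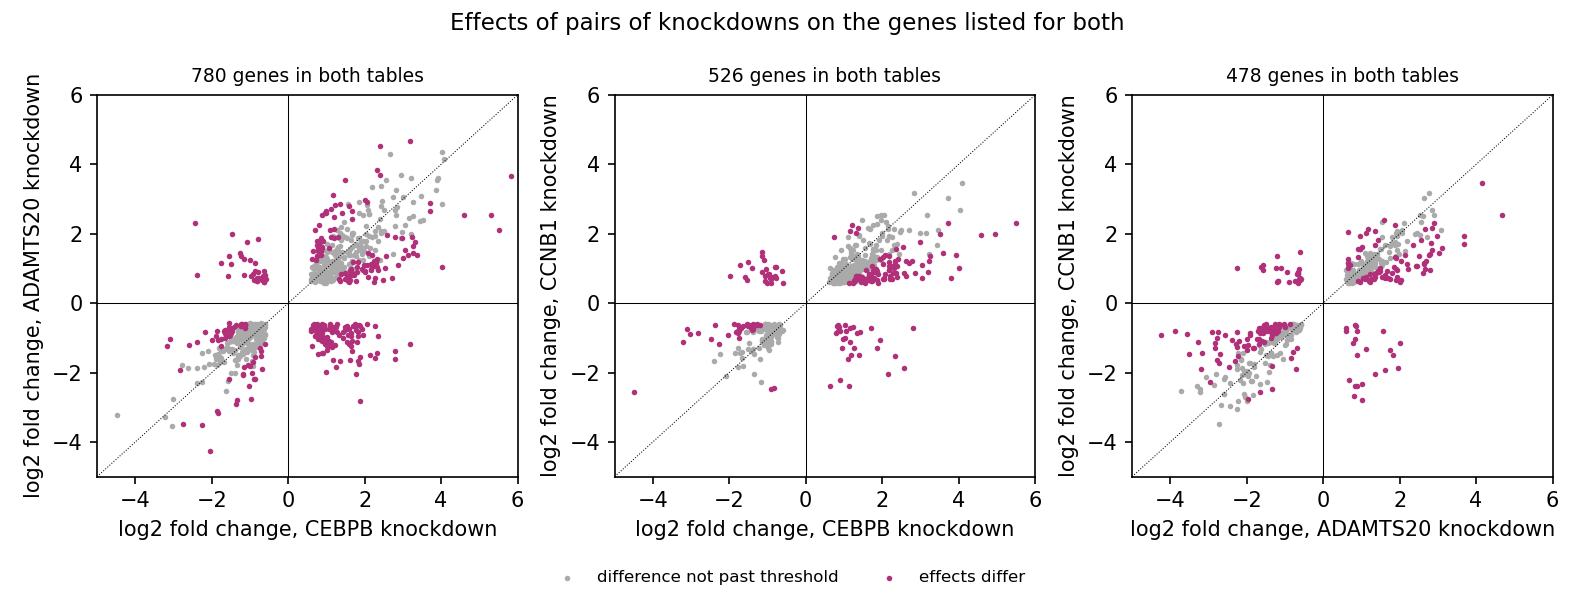
Log2 fold changes after one knockdown against those after another, for the 780, 526 and 478 genes listed in both tables of a pair, with 1 point per gene and colour for genes whose effects differed (321, 191 and 208). Most points lie in the quadrants where both knockdowns moved a gene the same way (80.9%, 89.4% and 90.4%). For the last pair, which shares its controls, 96.8% of simulated unchanged genes past the fold limit in both did so too. A simulation gave a mean of only 3.70 such genes of 478.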

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

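Tests chosen after the result was seen were those of an effect of shRNA transduction, of the shared control libraries and of a response to any knockdown hairpin, the GC corrections of lists and of the covariance, and the G2/M percentile after a GC trend, and the simulated share of genes past the fold limit.

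Knockdown effects that differed between experiments were found by limma's test of the difference in 321 genes for CEBPB against ADAMTS20, 191 for CEBPB against CCNB1 and 208 for ADAMTS20 against CCNB1. Genes with opposite directions numbered 149, 56 and 46. The CEBPB experiment had other control libraries, so target and experiment cannot be told apart in the pairs with CEBPB. Levels differed as well, with a mean for FLT4 of 2316 normalized counts in the CEBPB and 12336 in the CCNB1 experiment. Among genes with a mean of at least 200 normalized counts over the libraries of a pair, the 5 largest differences each way in log2 fold change, CEBPB minus ADAMTS20, were 4.42 for PRR9, 3.49 for OTOF, 3.39 for OAS2, 2.98 for PAEP, 2.93 for SRCIN1 on the positive side and -3.48 for PECAM1, -2.82 for SYBU, -2.72 for MICB, -2.66 for DSC3, -2.63 for RFLNB on the negative side, with SE from 0.20 to 0.63 and adjusted p from 9.68e-11 to 1.30e-04. Under the same limit they were, for CEBPB minus CCNB1, 4.46 for CCKBR, 3.51 for PRR9, 3.50 for MAGEA4, 3.20 for OAS2, 3.07 for MX1 on the positive side and -2.59 for PLA2G7, -2.43 for SPINK5, -2.33 for SERPINB7, -2.14 for SCUBE1, -2.10 for FLT4 on the negative side, with SE from 0.22 to 0.64 and adjusted p from 5.98e-08 to 7.63e-04. For ADAMTS20 minus CCNB1, again with a mean of at least 200, they were 3.83 for CCKBR, 3.81 for NDN, 3.25 for MAGEA4, 3.24 for MAGEA3, 3.14 for PECAM1 on the positive side and -3.33 for EBI3, -3.28 for ADAMTS20, -2.67 for SCUBE1, -2.66 for MUC20, -2.59 for CORIN on the negative side, with SE from 0.11 to 0.29 and adjusted p from 9.13e-10 to 6.49e-06. ADAMTS20 is itself a targeted gene in that last pair.

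Each count was set beside those of the 10 splits of the 6 libraries into 3 and 3. The real split gave 2603, 2037 and 1430 genes, and the highest of the other splits gave 0 by limma in each experiment (70, 20 and 37 genes at an unadjusted p under 0.05). For the differences, taken over knockdown libraries centred on their controls, the real split gave 429, 268 and 201 genes and the highest other 0 (21, 27 and 25 unadjusted). In every case 1 of the 10 splits reached the real count, and 10 splits cannot give a share under 0.1. Listed genes had been chosen by the authors for the real split.

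Genes called after CCNB1 knockdown differed in GC content by direction, with a gap of -15.9 percentage points between genes that rose and fell and a rho of -0.423 with the log2 fold change across genes. A GC bias between libraries is a candidate explanation for part of this set, because both limits written before the result was seen were passed. Libraries within a group also differed along GC, with rho from -0.706 to 0.622 in the CCNB1 table. In the CEBPB table that rho ranged from -0.716 to 0.726, yet the gap between genes that rose and fell was only -1.15 percentage points. A spread along GC within groups thus does not by itself go with a gap. A length bias and a biological effect of targeting CCNB1, whose own fall the table does not show, stay open, the former with a ratio of median lengths of 1.46 and a rho of 0.161 that lie between the limits written for and against it. The listed G2/M genes lay at percentile 93.86 of random sets after a length trend (93.24 to 95.1 without 1 gene) and at 77.45 after a GC trend. The limit written against a G2/M change, the middle 95% of random sets, was met, but it was wrongly set: every background gene had been chosen for a change, so lying among them cannot exclude one, and relative depth and group went together in this table.

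Interferon response genes rose after CEBPB knockdown by a median log2 fold change of 2.16 over 28 genes. A single library with a high interferon level is argued against, because the median without any 1 knockdown library was at least 2.09. An equal fold rise from shRNA transduction in all experiments is argued against as the whole cause. Of 18 gene comparisons with another knockdown, 88.9% showed a larger rise after CEBPB knockdown. These are 9 comparisons with each other knockdown against the same shared controls, so they are not independent. A rise is measured from each experiment's own controls, so a lower interferon level in the CEBPB controls would also enlarge it. For OAS2 the mean over the 6 libraries was 220, 214 and 274 normalized counts for CEBPB, ADAMTS20 and CCNB1. Its log2 fold changes were 5.51, 2.11 and 2.31, so its CEBPB controls started lower. MX1 likewise had a mean of 925 for CEBPB and 1115 for CCNB1, with log2 fold changes of 3.80 and 0.72. Each experiment was normalized separately, and the other interferon genes were not compared this way. A response to transduction from unlike control levels is therefore not excluded. An off-target or sequence-dependent effect of the hairpin cannot be told apart from an effect of lower CEBPB for this rise of 2.16, because the labels give no values for a second hairpin and the table does not show a fall of CEBPB. A biological response to lower CEBPB stays open as a hypothesis and was not tested.

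ADAMTS20 and CCNB1 knockdown moved 90.4% of their shared listed genes the same way, a share that unchanged groups selected against the same controls also reach (96.8% of 370 simulated genes past the fold limit in both, pooled over 100 draws); a draw gave a mean of 3.70 and at most 10 such genes, while all 478 listed genes passed that limit. For genes also listed for CEBPB, the shared control libraries are argued against as the whole cause, because 94.3% of the 229 genes with 1 direction in both of these tables had it in the CEBPB table too, whose controls are other libraries; over all 254 genes listed in the 3 tables, 85.0% had 1 direction throughout. For the 224 genes not listed for CEBPB, with a covariance of 1.91, the shared controls cannot be told apart from shared biology; the simulated covariance of at most 0.0397 allows for random spread alone, and the covariance over all 478 genes was 1.49 after a GC trend was removed. A response to any knockdown hairpin against the control hairpin may contribute, since the same 94.3% in a table with other controls is what it needs. A shared effect of targeting either gene on EVT differentiation gives the same prediction and stays open.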

How the results depend on the processing

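Alternatives chosen after the data were seen were the pseudocounts, the filter on low values, the fit with no mean-variance trend, Fisher's exact test of lists and the length and GC corrections. With an absolute log2 fold change of at least 1, called genes fell to 1403, 1074 and 567 for CEBPB, ADAMTS20 and CCNB1, and genes called in both tables with the same direction to 301 (CEBPB and ADAMTS20), 171 (CEBPB and CCNB1) and 213 (ADAMTS20 and CCNB1), since fewer genes meet a stricter limit. Camera with an estimated inter-gene correlation gave 0 lists in each experiment, and fry gave 25, 23 and 16. Fry does not compare lists with other genes, and every gene had been selected for a change. With a replicate block, 2 lists passed for CEBPB, 6 for ADAMTS20 and 3 for CCNB1, and 2603, 2037 and 1430 genes; for CEBPB the syncytiotrophoblast and hypoxia lists were lost (adjusted p = 0.0769 for both), and the cause was not tested. Correlations of libraries with the same number were -0.64, 0.15 and -0.06 for CEBPB, 0.46, -0.18 and 0.07 for ADAMTS20 and 0.40, 0.48 and -0.13 for CCNB1, so the numbers were not taken to pair samples. In pre-ranked camera after the GC correction, the steroid list for CEBPB (adjusted p = 0.0463) and the hypoxia list for ADAMTS20 (0.0353) also passed. Neither passed with an estimated correlation, and the form of the test differed as well as the correction. Leaving out 1 library gave 2 to 6 lists for CEBPB, with 2 without control replicate 2, where the syncytiotrophoblast and the hypoxia lists both had an adjusted p of 0.0535; the cause was not tested. The same ranges were 5 to 6 lists for ADAMTS20, 2 to 3 for CCNB1, 2600 to 2603, 2035 to 2037 and 1410 to 1430 called genes in the order of the experiments, and 287 to 334, 156 to 210 and 174 to 219 differing genes. The ADAMTS20 level ranged from -2.52 to -2.04. All 4476 alternative values of the 396 named results kept their direction and side of the threshold. The authors had selected the listed genes on the same libraries, and the largest changes were picked from these values. Both favour that outcome, so it is not independent evidence. Other normalizations, DESeq2, voom and a filter on CPM were not run because they need unselected counts, and no mitochondrial gene was listed to leave out; fits over 12 or 9 libraries stood in for 18. Genes outside the tables and total depth limit what can be said of unlisted genes.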

Other observations

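Apart from CGA, the genes described here were chosen after their values were seen. CGA and the chorionic gonadotropin beta subunit genes CGB3, CGB5, CGB7 and CGB8 went opposite ways after CEBPB and ADAMTS20 knockdown (n = 3 libraries per group), with no test of them as a group. CGA had a log2 fold change of 1.08 ± 0.22 after CEBPB knockdown and -0.75 ± 0.13 after ADAMTS20 knockdown. CGB3, CGB5 and CGB8 had 0.67 ± 0.22, 0.65 ± 0.22 and 0.59 ± 0.22 after CEBPB knockdown and -0.74 ± 0.13, -0.74 ± 0.13 and -0.74 ± 0.13 after ADAMTS20 knockdown. Limma's tests of the difference for CGB3, CGB5 and CGB8 gave adjusted p of 2.72e-05, 3.09e-05 and 3.51e-05. CGB7 had 1.27 ± 0.18 and -0.83 ± 0.08, with an adjusted p of 8.05e-08 for the difference, while CGB1 (1.34 ± 0.19) and CGB2 (1.55 ± 0.17) were listed for CEBPB alone. CGB genes are near-identical copies whose reads cannot be told apart with certainty, so they are not independent of each other.

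The NOTCH ligand DLL4 rose after CEBPB knockdown (log2 fold change 1.25 ± 0.20) and fell after ADAMTS20 (-1.85 ± 0.18) and CCNB1 knockdown (-1.29 ± 0.22). Its effect differed between CEBPB and ADAMTS20 knockdown by 3.10 ± 0.27 (adjusted p = 1.37e-08) and between CEBPB and CCNB1 knockdown by 2.54 ± 0.30 (adjusted p = 6.39e-06). DLL1, another NOTCH ligand, fell in all 3 experiments, with -2.08 ± 0.28 after CEBPB, -1.76 ± 0.32 after ADAMTS20 and -2.11 ± 0.27 after CCNB1 knockdown. The pregnancy-specific glycoprotein genes PSG1 and PSG4 were higher after both CEBPB and CCNB1 knockdown, with PSG1 at 1.24 ± 0.18 and 1.00 ± 0.15 and PSG4 at 1.19 ± 0.16 and 0.99 ± 0.14, and reads shared among these copies leave each value uncertain.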
